A study of Mus musculus with 2 samples.

How the data were processed

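DNase-seq libraries from the left cerebral cortex of 2 male B6CASTF1/J mice of 25 days were analysed, 1 library per animal; the labels call them biological replicates, and their replicate numbers come from the labels. There was 1 group and no contrast. Per the file headers, all files were made on mm10 from filtered alignments of 1 library each, with no pooling; the aligner, peak caller, its version and its threshold are not given in the sources used here. For each library the authors deposited 2 peak lists, a list of intervals with a false discovery rate and a list of footprints.

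Peak height is a signal the authors deposited with each peak, in cuts per 1000000 cuts of the library; it was used to describe and rank peaks within a list. All heights of a library were whole multiples of 1 step (100% within 0.05 of a step), and the depth is the inverse of that step, on the reading that 1 step is 1 cut. The file headers do not state the depth. The column for the summit held 75 in every row, so midpoints were used in its place. The interval files hold a q-value (false discovery rate of the cut rate) that the authors deposited, listed only under 0.05, over 40.7 Mb in replicate 1 and 82.7 Mb in replicate 2. The footprint files hold a constant q-value of 0.01, per the file headers an output derived from the alignments and the interval file. Because no file used here holds cut counts per base, the planned promoter cut levels, the differences between replicates by gene list and the correlation of cuts were not computed, and footprints could not be ranked.

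The plan made before the data were examined took the narrower of the 2 peak lists as the main one. Median widths were 200 and 200 bp in replicate 1 and 201 and 204 bp in replicate 2, so the smaller mean width was used, a measure chosen after the files were seen. The main list is also the shorter one (76699 against 128318 peaks, and 154942 against 242641). Every main peak held a base with a q-value of at most 0.001, against 62.7% and 66.3% of the longer lists. Peaks were kept on the 19 autosomes, X and Y.

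Genes and TSSs came from GENCODE mouse release M21 and sequence from GRCm38.p6, the build of mm10; no interval ran past the end of its chromosome. A promoter was 500 bp either side of any TSS of a protein-coding gene, and 21911 gene symbols were used. The 26 gene lists and 20 consensus sequences were fixed before the data were examined. Outside the olfactory receptors 488 listed genes matched and 6 did not, of which 5 are noncoding. Overlap meant at least 1 bp, computed in NumPy 2.4.6 and pandas 2.3.3 under Python 3.11.15 and checked with bedtools 2.31.1, which gave the same counts. Chance overlap was the mean of 1000 random placements of a list on the same chromosomes. Density used sequenced bases. Lists were tested per library with Fisher's exact test (SciPy 1.17.1), two-sided, with Benjamini-Hochberg adjustment over lists, and called only at an adjusted p under 0.05 in the same direction in both libraries. Footprints were extended by 5 bp and set against windows of the same width 100 bp away in the same peak and clear of footprints; 42.6% and 40.1% of footprints had such a window. Consensus sequences were searched on both strands. Intervals are 95% Wilson intervals and cover counting error only, since reads are not independent molecules. Figures were drawn with Matplotlib 3.10.9.

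Named genes followed a rule fixed beforehand. From each list these were the 3 members with the highest mean percentile rank of their strongest promoter peak and up to 3 with no promoter peak in either library, in alphabetical order because no lower signal could be read; not every one is printed, and some are not reported here. The rule also took the 10 genes with most shared distal peaks per 100 kb, the 5 peaks with the best mean rank, and all consensus sequences. The part of the rule for the replicate difference was not applicable. On simulated data with real list sizes, 76.2% of 600 lists planted at a share of 95% and 80.7% of 600 planted at 20% were called in both libraries, and 1 of 1300 unchanged lists was. The simulation drew the 2 libraries independently. In the data 12938 genes had a promoter peak in both libraries and 84 in replicate 1 alone, so these rates do not carry over to the real calls. All 2000 planted copies of the CTCF, NEUROD and AP-1 sequences were found in 20000 windows each. Alternatives covered a 1000-bp promoter window, the better-scored 50% of each list, the longer peak lists, equal list sizes, a reciprocal overlap of 50%, autosomes only, other footprint controls and leaving out each library. Equal list sizes for location and chromosomes, the reversed consensus sequences, the settings for named genes and leaving out a library for footprints were added after the data were seen.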

Results

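DNase I cuts DNA where it is not wrapped around a nucleosome, so sequenced cut sites map open chromatin, and short protected stretches inside open regions (footprints) mark bound protein. The assay was run on the left cerebral cortex of male B6CASTF1/J mice, a first-generation cross between C57BL/6J and the wild-derived strain CAST, at 25 days of age. There was 1 group with 2 biological replicates, each a library from a different animal, and no treatment or second tissue. The results therefore describe the accessible chromatin of this tissue and how far the 2 libraries agreed. With 1 library against 1, no difference between the animals had a replicate test. Heights in the deposited lists, in cuts per 1000000 cuts of the library, moved in whole steps. Read as 1 cut each, these steps gave a depth, in units of 1000000 cuts, of 152.0 in replicate 1 and 280.5 in replicate 2, a ratio of 1.85. All heights given here are in that unit.

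Replicate 1 held 76699 peaks and replicate 2 held 154942 (mean 115820 ± 55326, SD, n = 2). They covered 15.6 Mb and 32.4 Mb, or 0.590% and 1.22% of the sequenced bases of mm10. The mean peak was 206 bp wide in replicate 1 and 211 bp in replicate 2. Of the replicate 1 peaks, 95.2% overlapped a replicate 2 peak by at least 1 bp (95% Wilson interval 95.1 to 95.4%), against 2.46% for the same peaks placed at random on their chromosomes. Of the replicate 2 peaks, 47.2% overlapped a replicate 1 peak (46.9 to 47.4%), against 1.22% at random. Cut to the 76699 highest peaks of each library, the share was 78.6% for replicate 1 and 78.4% for replicate 2. The covered bases had a Jaccard index of 0.396. Across 71950 pairs of overlapping peaks, heights had a Spearman rho of 0.892 and a Pearson r of 0.914 on the log2 scale. Those are correlations across peaks, which are not independent replicates. Peaks of replicate 2 without a partner were lower, with a median height of 0.463 against 1.28 for shared ones.

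Most peaks lay away from promoters. On average 40.6% ± 2.45 (SD, n = 2) of peak midpoints were intergenic and 35.8% ± 3.96 were intronic. A further 19.3% ± 6.54 lay within 500 bp of the transcription start site (TSS) of a protein-coding gene and 4.28% ± 0.131 lay in exons. The promoter share was 24.0% in replicate 1 and 14.7% in the deeper replicate 2. Replicate 2 peaks at promoters were shared with replicate 1 in 75.1% of cases, those in introns in 40.9% and intergenic ones in 43.6%.

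Genes of cortical excitatory neurons, the synapse and activity-dependent transcription had open promoters almost without exception. All 14 upper layer genes and all 26 activity-regulated genes had a promoter peak in both libraries, as did 30 of 31 synapse genes in replicate 1 and 31 of 31 in replicate 2. The excitatory neuron list had 16 of 17 genes with a peak in each library, 15 of them in both. Across all 21911 protein-coding genes the share was 59.4% in replicate 1 and 63.9% in replicate 2. The tallest promoter peaks of these lists belonged to Tle4, a corepressor of deep layer neurons (height 13.7 and 16.4 in replicates 1 and 2, chromosome 19, 14598121 to 14598560), and Jun, an AP-1 subunit (10.3 and 13.3, chromosome 4, 95052161 to 95052560). Among upper layer genes the transcription factor Pou3f3 reached 6.66 and 8.62 and Lmo4 reached 4.72 and 5.10. Camk2a, the calcium-dependent kinase of excitatory synapses, reached 4.10 and 5.10 (chromosome 18, 60925481 to 60925680), the NMDA receptor subunit gene Grin1 reached 3.98 and 4.19, and Nrgn reached 3.34 and 4.35. The synaptic adhesion gene Nlgn2 reached 8.09 and 8.87, the calcium sensor gene Syt1 5.62 and 6.43, the activity-regulated gene Gadd45b 8.56 and 8.91, and the synaptic scaffold gene Homer1, in the same list, 7.91 and 7.66.

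By Fisher's exact test against all other protein-coding genes, two-sided and Benjamini-Hochberg adjusted over 26 lists, 6 lists were higher in both libraries. In replicates 1 and 2 the adjusted p was 1.33e-05 and 1.22e-05 for synapse genes, 9.82e-06 and 5.51e-05 for activity-regulated genes, 0.00508 and 0.0193 for excitatory neurons, 0.00329 and 0.00974 for upper layer neurons, and 6.77e-06 and 3.80e-05 for housekeeping genes. The deep layer list had 14 of 16 genes with a peak in replicate 1 (adjusted p = 0.0336, Fisher's exact test) and 15 in replicate 2 (0.0274); Nxph4 had none, and Pcp4 and Rprm were among its tallest. The mean difference from other genes was 29.0 percentage points. The call was lost with a 1000-bp window, where the difference was 27.1 points, and with equal list sizes and the better-scored 50% of each list, where it was 20.1 and 4.58. The 27 housekeeping genes, which every cell uses, all had peaks in both libraries, up to 11.7 and 11.3 at Rplp0, 10.5 and 11.2 at Vcp and 9.91 and 7.43 at Actb. Genes are the units of these tests, which describe these libraries and not the spread between animals.

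Promoters of interneurons, glia and vessels were open in part, and more of them in the deeper library; none of these 7 lists differed from other genes in both libraries. In 1 library alone, astrocyte genes were higher in replicate 2 (adjusted p = 0.0439, Fisher's exact test) and endothelial and mural cell genes lower in replicate 1 (0.00719 and 0.00211). Microglial genes had a peak in 9 of 22 cases in replicate 1 (40.9%, Wilson interval 23.3 to 61.3%) and 16 in replicate 2 (72.7%). Inhibitory neuron genes had 14 and 21 of 26, astrocyte genes 12 and 16 of 18, oligodendrocyte genes 8 and 13 of 20, and oligodendrocyte precursor genes 9 and 12 of 13. Endothelial genes had 6 and 11 of 22, and mural cell and fibroblast genes 4 and 8 of 19. With the 76699 highest peaks of replicate 2, the counts for that library were 6 microglial, 15 inhibitory neuron, 11 astrocyte, 7 oligodendrocyte, 7 precursor, 4 endothelial and 3 mural cell genes, and the endothelial and mural lists were lower than other genes in both libraries. Among the taller peaks of these lists were those at Clu (7.36 and 7.84), an apolipoprotein gene strong in astrocytes, at Maf (1.94 and 2.63), which encodes a factor of medial interneurons, and at the glucose transporter gene Slc2a1 of brain endothelium (2.93 and 2.51). The microglial transcription factor gene Irf8 reached 1.70 and 1.59, while Olig1 reached 1.52 and 1.98 and Pdgfra, the receptor of precursors, 1.38 and 1.41. No promoter peak was found in either library at Lhx6, Nxph1 or Sp8 among interneuron genes, Aqp4 or Fgfr3 among astrocyte genes, Aspa, Ermn or Mag among oligodendrocyte genes, Ctss, Gpr34 or Itgam among microglial genes, and Cldn5, Emcn or Eng among endothelial genes.

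Promoters of genes of other organs, of the hypothalamus, midbrain and brainstem, of the choroid plexus and of the body axis were mostly without a peak. Only 1 of 39 Hox genes had a promoter peak in replicate 1 and 2 in replicate 2, Hoxa7 in both and Hoxc5 in replicate 2 (2.56% and 5.13%, adjusted p = 3.79e-13 and 1.66e-13, Fisher's exact test). Liver genes had 0 of 19 in replicate 1, with an upper Wilson bound of 16.8%, and 2 in replicate 2, Afp and Apob; Alb, Ahsg and Ambp had none. Heart and skeletal muscle genes had 2 and 5 of 19, with Tnni3 the tallest (0.829 and 0.763). Erythroid genes had 4 and 4 of 14, with the erythropoietin receptor gene Epor at 1.64 and 1.52 and no peak at Gata1 or Alas2, and lymphocyte genes had 3 and 3 of 13, with Lck at 1.28 and 1.19 and no peak at Cd3d or Cd3e. Of 1134 olfactory receptor genes, 15 (1.32%) and 41 (3.62%) had a peak; Olfr1414 was the tallest at 1.64 and 2.52. Genes of hypothalamus, midbrain and brainstem had 2 and 6 of 18, Tph2 and Pitx3 in both libraries, with none at Avp, Fev or Gbx2. Choroid plexus and ependyma genes had 2 and 4 of 15, the cilia factor gene Foxj1 standing at 4.39 and 5.69 and Prlr at 0.717 and 1.14. These 8 lists were lower in both libraries, with adjusted p (Fisher's exact test) from 3.79e-13 to 0.0386 in replicate 1 for 7 of them; for olfactory receptors it was too small to be computed. With the longer peak lists the hypothalamus and choroid plexus calls were lost (mean differences of -30.1 and -32.9 percentage points, against -39.5 and -41.7), and with a 1000-bp window the choroid plexus call (-33.6).

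**Figure D1:**
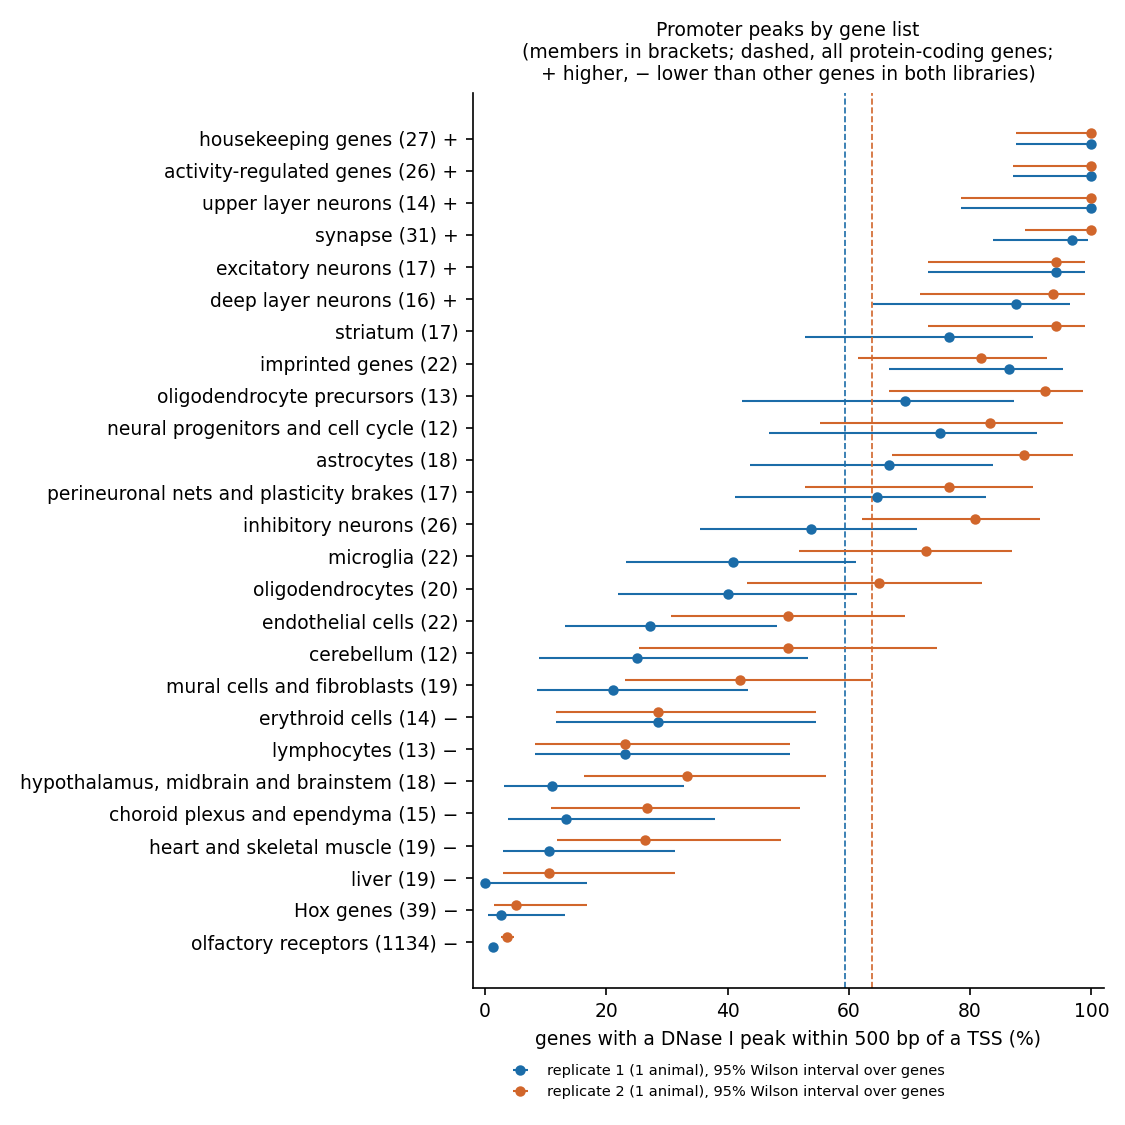
Percentage of the genes of each of 26 lists with a DNase I peak within 500 bp of a TSS, per library (blue, replicate 1; orange, replicate 2), with 95% Wilson intervals over genes. The 6 lists marked + lie above and the 8 marked − lie below the other genes in both libraries; dashed lines show all protein-coding genes (59.4% and 63.9%).

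The last lists did not differ from other genes in both libraries. Striatal genes had peaks in 13 and 16 of 17, among them Pde10a (3.26 and 4.87) and Rgs9 (3.18 and 3.21), with none at Six3. Cerebellar genes had 3 and 6 of 12, Cbln1 the tallest at 2.33 and 2.10, with none at Barhl1, En1 or En2, and were lower in replicate 1 alone (adjusted p = 0.0306, Fisher's exact test). At equal list size and with the better-scored 50% of each list the cerebellar list was lower in both libraries, by a mean difference of -37.2 and -38.2 percentage points. Progenitor and cell cycle genes had 9 and 10 of 12, with Top2a at 5.47 and 7.55, Sox11 at 3.87 and 4.58 and none at Nes or Neurog2. Genes of perineuronal nets and other brakes on plasticity had 11 and 13 of 17: the axon growth inhibitor gene Rtn4 reached 7.95 and 7.44 and Plat 5.22 and 5.20, while Acan, the main net proteoglycan, Chst3 and Mmp9 had no promoter peak. Imprinted protein-coding genes had 19 and 18 of 22, led by Ube3a (6.84 and 5.68), Inpp5f (5.57 and 6.32) and Peg3 (3.72 and 3.88), with none at Igf2, Ndn or Zdbf2. By Fisher's exact test imprinted genes were higher in replicate 1 alone (adjusted p = 0.0164) and striatal genes in replicate 2 alone (0.0193). Of the imprinted noncoding genes, Meg3, Kcnq1ot1 and Peg13 had a peak in both libraries and H19 and Airn in replicate 2 alone.

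Of the peaks in both libraries, 53890 lay more than 500 bp from any TSS. Among 10152 protein-coding genes of at least 20 kb, the median density of these within the gene body was 1.98 per 100 kb and the 90th percentile was 6.52. Fmnl1, which encodes an actin-nucleating formin (chromosome 11, 103171107 to 103198901), had the highest density, with 7 such peaks or 25.2 per 100 kb, followed by Glt8d2 (9 peaks, 22.4 per 100 kb) and Bop1 (5 peaks, 20.6). Gcnt4, Peg3, Gucy2g, Npcd, Sfi1, the potassium channel gene Kcnk9 and Dmtn, which encodes the actin-bundling protein dematin, followed with 19.1 to 17.2 per 100 kb. In Fmnl1 most of the shared peaks were in the last part of the gene, between 103192241 and 103197760.

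**Figure D2:**
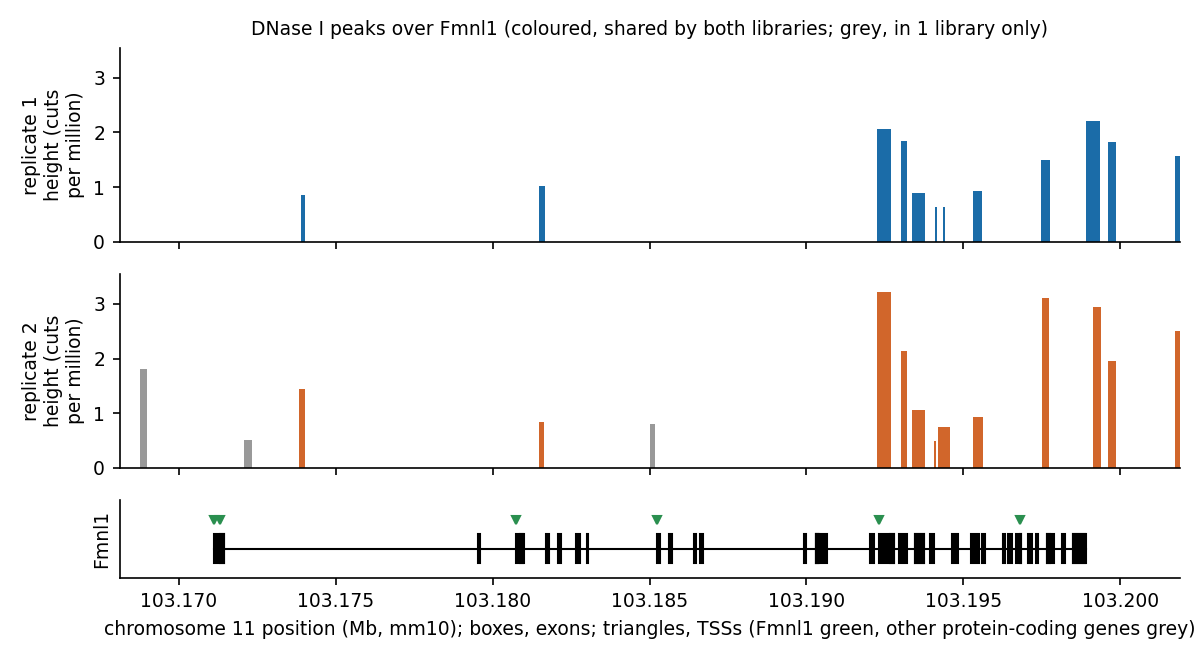
Peaks over Fmnl1 on chromosome 11 (x axis, position in Mb, mm10), with height in cuts per 1000000 cuts on the y axis for replicate 1 (top) and replicate 2 (middle); coloured bars overlap a peak of the other library and grey bars do not, and the bottom track shows exons and TSSs. The tallest of the gene's peaks, at 103192241 to 103192700, stood at 2.06 in replicate 1.

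Of the 5 tallest peaks by rank in both libraries, the first lay in an annotated rRNA gene (chromosome 17, 39846781 to 39846920, heights 45.8 and 62.6), where reads from many near-identical ribosomal copies can pile up. Repeated sequence was not examined at the other peaks. The others were intergenic on chromosome 3 (5860361 to 5860530; 26.6 and 41.9), in an exon of Lars2, which encodes mitochondrial leucyl-tRNA synthetase (chromosome 9, 123461901 to 123462140; 25.3 and 36.2), at the promoter of Hjurp, inside the annotated span of Trpm8 (chromosome 1, 88277541 to 88277760; 20.7 and 23.8), and intergenic on chromosome 6 (49236421 to 49236620; 20.4 and 30.4), 7303 bp from Tra2a.

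The X chromosome, present in 1 copy in males, carried fewer peaks per Mb than the autosomes. It had 11.9 peaks per Mb in replicate 1 and 24.9 in replicate 2, against 31.2 and 63.0 on the autosomes, a ratio of 0.387 ± 0.0106 (SD, n = 2). With the better-scored 50% of each list the ratio was 0.228. The Y chromosome held 17 and 49 peaks, or 0.193 and 0.556 per Mb. That density is over all its sequenced bases, and how much of Y the reads could be mapped to was not examined. Of the X-linked protein-coding genes, 45.0% and 48.5% had a promoter peak, against 60.6% and 65.1% of autosomal genes.

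**Figure D3:**
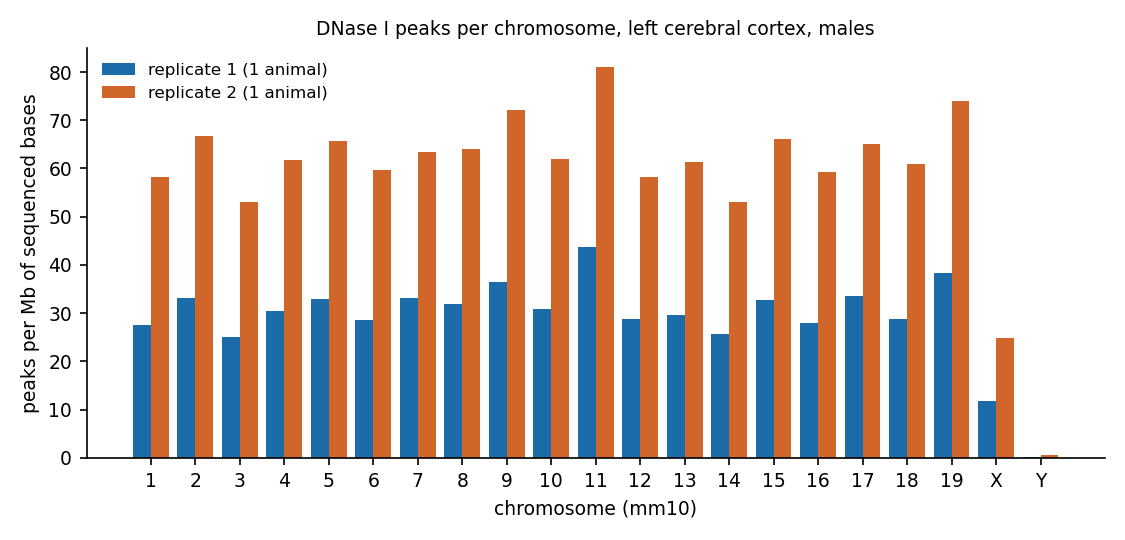
Peaks per Mb of sequenced bases (y axis) on each mm10 chromosome (x axis), 1 bar per library. X stood at 11.9 and 24.9 peaks per Mb and Y at 0.193 and 0.556, against 31.2 and 63.0 over the autosomes.

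Footprints numbered 277979 in replicate 1 and 630050 in replicate 2, with a median width of 9 bp in both. On average 71.0% ± 0.296 (SD, n = 2) overlapped a peak, and 88.6% ± 1.40 of peaks held at least 1 footprint, with 2.73 ± 0.211 footprints per peak. Of the replicate 1 footprints, 60.1% overlapped one of replicate 2, and 24.8% the other way. For footprints inside peaks that had room for a 100-bp shift, 67.0% of replicate 1 footprints overlapped one of replicate 2, against 40.7% at the shifted positions, and for replicate 2 31.4% against 20.9%. With a reciprocal overlap of at least 50% the shared shares were 35.7% and 15.7%, and inside shared peaks 45.9% of replicate 2 footprints were shared.

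Footprints were enriched in the consensus sequences of the insulator protein CTCF, of NEUROD, of activity-regulated factors and of general promoter factors. Which proteins were bound there was not measured. Of 20 consensus sequences, 11 were more frequent in footprints than in windows shifted by 100 bp inside the same peaks, in both libraries. Shares are of the footprints that had such a window, 42.6% of all in replicate 1 and 40.1% in replicate 2. The CTCF consensus CCASYAGRKGGC was in 726 of 118517 footprints in replicate 1 (0.613%, Wilson interval 0.570 to 0.659%) and 731 of 252694 in replicate 2 (0.289%), 66-fold and 60.9-fold above the shifted windows (adjusted p = 5.15e-198 and 9.49e-198, Fisher's exact test, two-sided). The NEUROD sequence CCATCTGK was 5.07-fold and 4.97-fold more frequent (1.31% and 1.27% of footprints; adjusted p = 2.49e-201 in replicate 1 and too small to be computed in replicate 2, Fisher's exact test). EGR sites, bound by factors that neuronal activity induces, were 14.3-fold and 30.2-fold more frequent, CREB sites 11.8-fold and 20.1-fold, and AP-1 sites, in 1.06% and 1.56% of footprints, 1.81-fold and 2.27-fold. RFX sites were in 85 and 133 footprints against 2 and 1 shifted windows, and NRF1 sites in 161 and 110 against 0 and 3. SP/KLF sites were 5.82-fold and 9.38-fold, YY1 sites 2.85-fold and 2.86-fold and ETS sites 2.02-fold and 1.90-fold more frequent; ETS was no longer called among peaks more than 500 bp from a TSS. NFI sites were in 12 and 32 footprints and in no shifted window, which puts them at least 4-fold and 10.7-fold higher against 3 windows. The size of the excess depended on the windows: with a 50-bp shift the mean excess of CTCF was 1.54 percentage points, against 0.444 with 100 bp, and with footprints as deposited, without the added 5 bp, that of AP-1 was 0.162 against 0.673 and that of NEUROD 0.5001 against 1.04, each still called.

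PU.1 sites, those of a myeloid and microglial factor, and GATA sites were less frequent in footprints than in shifted windows, at 0.532 and 0.589 times and 0.340 and 0.292 times the control. MEF2, NFY and SOX sites passed the test in 1 library each: MEF2 was higher in replicate 2 (1.38 times the control, 1.13 in replicate 1), NFY higher in replicate 1 (1.28, against 1.11 in replicate 2) and SOX lower in replicate 1 (0.627, against 0.870 in replicate 2). With footprints as deposited SOX was lower in both libraries, and with control windows shifted by 50 bp SOX was lower and NFY higher in both. REST, HNF4 and GRHL sites passed in neither library. REST was in 2 and 3 footprints against 2 and 1 shifted windows, and GRHL in 7 and 12 against 10 and 15. Counts this low cannot tell a modest excess from none. The HNF1 sequence was in 0 footprints in both libraries, which allows up to 0.00253% and 0.00119% (3 footprints, counting error only). The consensus sequences were also read backwards, with the same bases in the opposite order. The SP/KLF sequence reads the same both ways, so this control could not be applied to it. Reversed CTCF, RFX, NRF1 and NFI were in at most 1 footprint and 2 shifted windows per library, too few for a call. None of reversed AP-1, EGR, NEUROD, CREB, ETS and YY1 was higher in both libraries; EGR was higher in replicate 2 alone (2.19 times the control), and AP-1 was lower in both (0.730 and 0.771). Reversed PU.1, GATA, MEF2 (0.50 and 0.621) and SOX (0.278 and 0.362) were lower in both as well. Reversed GRHL was higher, and reversed NEUROD, CREB, NFY and HNF4 lower, in replicate 2 alone. Footprints also had a higher GC content than the shifted windows, 57.9% against 54.0% in replicate 1 and 53.2% against 49.1% in replicate 2, and DNase I itself prefers some sequences.

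**Figure D4:**
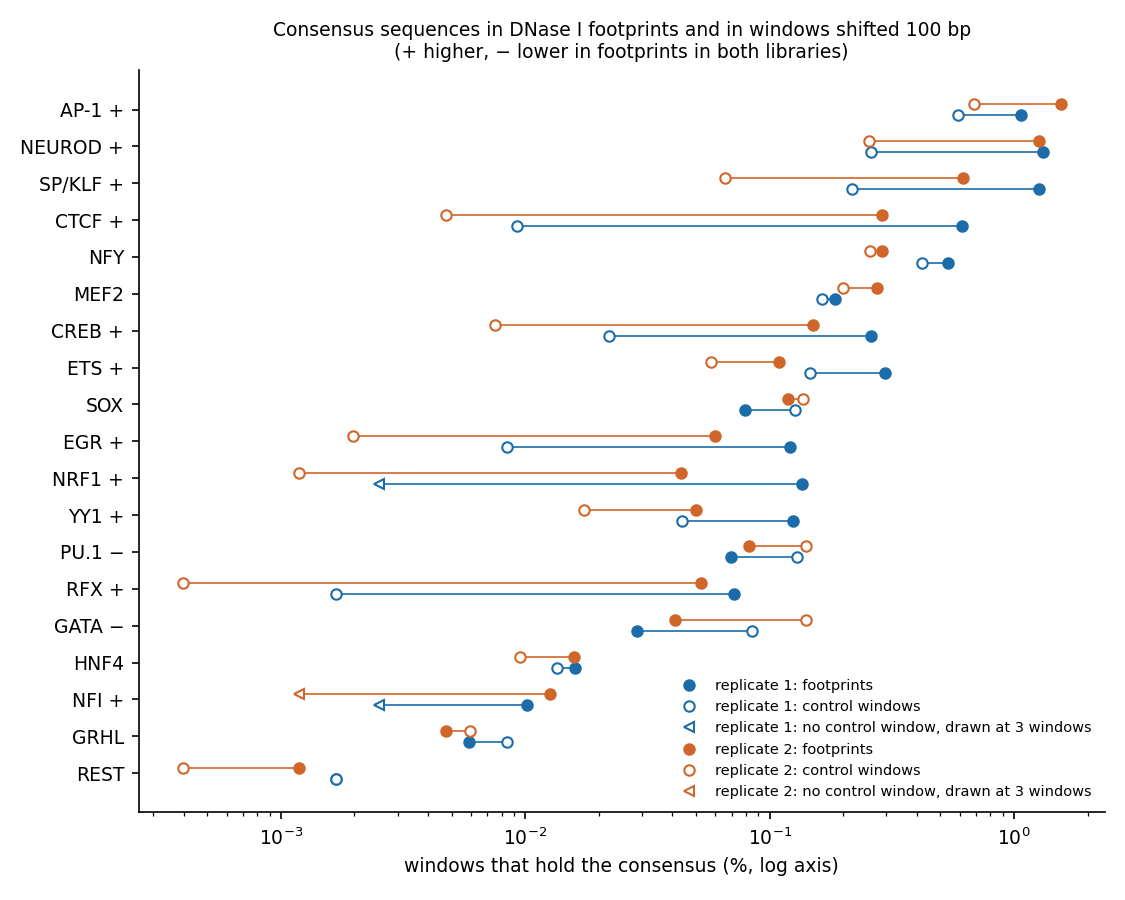
Percentage of footprints (filled) and of windows shifted by 100 bp in the same peaks (open) that hold each consensus, per library, on a log axis; left-pointing triangles mark no window, drawn at 3 windows, and HNF1, found in 0 footprints, is not drawn. CTCF stood at 0.613% and 0.289% of footprints, and GATA and PU.1 below their controls.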

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

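The equal list sizes for location and chromosomes, the settings for named genes and the leave-one-out values for footprints were chosen after the data were seen. Of 71 recomputed summary values, 45 stayed the same and 26 moved. Counts were the same within 1.5 times, overlap shares within their Wilson interval, and other shares and densities within 1 SD of the 2 libraries. Leaving out 1 of 2 libraries always stays within that SD, so such shares and densities could not move. Of 789 values for single lists, genes and sequences, 687 were the same, 63 moved, 20 gained and 7 lost a call, and 12 turned, none of them a called result. With the better-scored 50% of each list there was a mean of 57910 peaks per library, 98.5% of replicate 1 and 49.0% of replicate 2 peaks were shared, 28.2% of peaks were at promoters, 3.97% in exons and 34.3% intergenic, and the X and Y densities were 0.228 and 0.00502 of the autosomal one. Equal list sizes gave shares of 78.6% and 78.4%, 4.11% in exons, 37.9% intergenic and ratios of 0.304 for X and 0.00507 for Y. Reciprocal overlap of 50% gave 77.8% and 38.5% of peaks and 35.7% and 15.7% of footprints, the longer lists 91.0% and 48.1% of peaks, and a 1000-bp window 3.42% in exons. Inside shared peaks there was a mean of 235274 footprints per library, 68.2% and 45.9% of them shared. Leaving out a library put peaks between 76699 and 154942 and footprints between 277979 and 630050. The number of lists higher ran from 5 to 8 (6 in the main setting) and lower from 6 to 12 (8); the deep layer, choroid plexus and hypothalamus calls were the ones lost. The endothelial, mural and cerebellar lists were lower in both libraries at equal size (-35.4, -39.7 and -37.2 percentage points) and with the better-scored 50% (-41.2, -44.3 and -38.2), where microglia were too (-34.4), and astrocytes were higher with the longer lists (28.3). In percentage points against other genes, the uncalled interneuron list turned to -8.65 with the better-scored 50%, -2.29 at equal size and ran from -5.59 without replicate 2 to 16.9 without replicate 1, precursors to -8.65 and striatum to -7.74 with the better-scored 50%, oligodendrocytes to 1.32 and microglia to 8.83 with the longer lists, while leaving out a library moved these from -19.4 to 1.12 and from -18.5 to 8.85. For footprints as deposited MEF2 turned to -0.000497 and HNF4 to -0.00062, and away from TSSs REST turned to -0.000401; 10 to 12 sequences were higher (11) and 2 to 3 lower (2). Among called sequences the excess moved by over 1.5 times for CTCF with a 50-bp shift (1.54 against 0.444 percentage points), for AP-1 (0.162 against 0.673), NEUROD, RFX, SP/KLF, ETS, YY1, PU.1 and GATA with footprints as deposited, all smaller, and away from TSSs for SP/KLF (0.213 against 0.798), NRF1 (0.0300 against 0.0891), ETS (0.00969 against 0.101), CREB, EGR and YY1, all smaller. Without replicate 1 it was 0.285 for CTCF, 0.0423 for NRF1, 0.0518 for ETS and 0.0325 for YY1, and without replicate 2 0.136 for NRF1. The cause of these moves was not tested beyond the shorter lists that the settings make. Promoter cut levels and replicate differences, and footprints ranked by score, were not run. In the deposited lists 1060 genes had a promoter peak in replicate 2 alone and 84 in replicate 1 alone, against 214 and 818 at equal list size; lists of 1 length do not part depth from other differences between the libraries, so what depth alone limits was not tested.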

Other observations

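The comparisons with length-matched lists, of promoter with distal footprints and of genes with a peak in replicate 2 alone, and the AP-1 test in windows of 1 width, were chosen after the data were seen. The rule for the spread in the AP-1 and X dose tests was also settled after their values were seen: an estimate had to meet the bound against its explanation by more than 1 SE, with a 95% interval that left out what the explanation needs. Had the whole 95% interval been held to that bound, both would have stayed undecided.

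Distal open chromatin was dense around activity-regulated genes, and several other lists also stood high among random lists matched on gene length. Each list was set against its own matched lists only. The percentiles were not adjusted over lists, and differences between the lists were not tested. Within 10 kb of the gene body, activity-regulated genes had a mean of 2.81 distal peaks shared by both libraries, 2.98 times the 0.942 of random lists matched on gene length (percentile 100 among 10000 such lists). The random lists were drawn from all other protein-coding genes, including the olfactory receptors, which had a mean of 0.101 distal peaks. The ratio was 2.00 for excitatory neuron genes (percentile 98.6), 1.81 for synapse genes (99.0) and 1.88 for genes of perineuronal nets and plasticity brakes (98.4), although 4 of 17 of the last had no promoter peak. Housekeeping genes, which are not specific to neurons, stood at 1.47 (96.2), upper layer genes at 1.57 (94.8) and striatal genes at 1.55 (93.6). Microglial genes stood at 1.42 (90.9), oligodendrocyte genes at 1.40 (90.4) and astrocyte genes at 1.40 (88.7). Heart and skeletal muscle genes stood at 1.34 (85.4) and deep layer genes at 1.26 (83.4). Inhibitory neuron genes stood at 0.825 (29.9), endothelial genes at 0.717 (14.2), Hox genes at 0.677 (8.01) and olfactory receptors at 0.125.

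Footprints near and far from TSSs differed in content. Distal footprints held the NEUROD sequence 7.56 times as often as footprints within 500 bp of a TSS in replicate 1 and 4.69 times in replicate 2, AP-1 6.23 and 3.77 times, CTCF 4.06 and 2.58 times and MEF2 3.91 and 4.57 times. Promoter footprints held ETS sites 22.8 and 20.5 times as often, SP/KLF 11.5 and 10.7 times, NRF1 7.39 and 8.36 times, NFY 5.83 and 4.79 times and YY1 5.52 and 8.83 times. CREB and EGR sites, of factors tied to neuronal activity, were on the promoter side too, at 3.58 and 3.23 times and 3.34 and 4.47 times. Each of these had an adjusted p under 0.05 in both libraries (Fisher's exact test, 20 sequences), with footprints as the units. The comparison had no shifted windows as a control. Promoters are GC-rich, so base composition could give part of these ratios, which was not tested. MEF2 and NFY were not called above their shifted windows in both libraries.

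More promoters of interneuron, glial and vascular marker genes held a peak in the deeper library. Of 78 interneuron, glial and vascular marker genes without a promoter peak in replicate 1, 36 (46.2%) had one in replicate 2. The share was 11.6% of 8811 other genes and 6 of 56 (10.7%) for liver, muscle, erythroid and lymphocyte genes; neither set was matched on CpG content, the former includes the olfactory receptors, and the shares were not used as a test. With equally long lists 7 of the 78 had one, and 16 genes of these lists that had a peak in replicate 1 had none in replicate 2. These lists were pooled after their counts were seen, and no difference in cell types between the animals was tested.

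At equal list size, 16413 peaks were in replicate 1 only and 16595 in replicate 2 only, and the former were more often at promoters (20.7% against 7.66%). Of both sets, 93.8% lay in the lower 50% of their list by height, as ranking noise near the end of a list would give, and 77.6% of the replicate 1 set lay in the full list of replicate 2. Heights correlated across pairs of peaks (rho 0.892), so peaks missing from 1 list would lie low in the other under other causes too. That share of 93.8% therefore cannot tell ranking noise from other causes. Matched on GC content, the promoter difference of 13.1 percentage points fell to 1.97 ± 0.374 (SE), as a GC bias between the libraries could give; promoters are themselves GC-rich, so that matching removes part of any true promoter difference, but distal peaks differed as well, at 50.4% and 48.1% GC in windows of 200 bp. AP-1 sites were 1.54 times as frequent in the distal replicate 2 set. That value cannot be told apart from the greater width of those peaks (1.69 times). In windows of 1 width, 200 bp, the ratio was 1.17 (95% interval 1.09 to 1.26). By the rule above this argues against the 1.5-fold difference predicted for such windows and leaves a smaller one open. In the full sets the median peak was 134 bp wide in replicate 1 and 220 bp in replicate 2. The windows therefore took in sequence beyond many replicate 1 peaks, so they do not decide AP-1 use inside peaks. A difference between the animals was not otherwise tested.

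CpG-rich promoters are open in many cell types, so CpG content could set the gene list results. Among 10000 lists matched on CpG content, the pooled neuronal, synapse and activity lists (96.2% and 98.1% with a promoter peak) stood at percentile 100 in both libraries against medians of 79.8% and 83.7%, and the pooled liver, muscle, erythroid and lymphocyte lists at percentile 1.09 or lower, which argues against CpG content as the whole cause for either. Taken singly, the synapse list (99.97 and 99.95) stood above the central 95% of matched lists in both libraries. The excitatory neuron list (99.6 and 98.2) stood above it in replicate 1, but its 94.1% in replicate 2 equalled the upper end. The microglial list (98.1 and 100) stood above it in replicate 2 and equalled the upper end in replicate 1. Its shares were 40.9% and 72.7%, against medians of 22.7% and 31.8%. The deep layer list (93.2 and 95.8) did not stand above it in both. The upper layer (98.7 and 96.7), activity-regulated (98.1 and 95.02) and housekeeping lists (98.1 and 95.2) were at 100%. So was the upper end of their matched range, so they could not have stood above it. Neither liver (1.38 and 7.87), muscle (3.33 and 20.3), lymphocyte (9.44 and 3.01), choroid plexus (0.61 and 5.29) nor erythroid genes (68.8 and 43.4) stood below it in both. That leaves CpG content open for all of these lists except the synapse list. The Hox list stood at percentile 0 in both libraries, 2.56% and 5.13% against medians of 84.6% and 87.2%, despite CpG-rich promoters. The hypothalamus, midbrain and brainstem (0 and 0.005) and olfactory receptor lists (0 in both) also stood below the central 95% in both. The cerebellar list (0.015 and 2.18) stood below it in replicate 1, but its 50% in replicate 2 equalled the lower end. For Hox genes a candidate explanation is silencing of the clusters in cortex, for which no mark was measured here.

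The low density of peaks on X goes with a lower signal. Peaks with the CTCF consensus were 0.595 and 0.552 times as high on X as on the autosomes (95% bootstrap intervals 0.488 to 0.651 and 0.479 to 0.654), as 1 copy of X in males would give. A lack of promoters is argued against as the whole cause, since distal peaks per Mb on X were also at most 0.379 of the autosomal density. The lower signal on X would itself lower the distal density, so a part played by fewer promoters stays open. A signal at 50% is argued against as the whole cause: X peaks at or above the autosomal median height were 0.563 (95% interval 0.518 to 0.611) and 0.510 (0.481 to 0.540) times as dense as autosomal peaks at double that height, where a dose effect alone would give about 1. Fewer regulatory sites on X may contribute and were not tested. Mapping of CAST sequence to the reference was not tested either, nor was the parent strain of the X examined.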
